A study of Homo sapiens with 8 samples.

How the data were processed

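Polysome profiling with RNA sequencing was applied to human acute myeloid leukaemia cells labelled Molm13 and U937. Per the labels' protocols, OGFOD1 was introduced with a lentiviral expression vector, cells were treated with cycloheximide, lysates were separated on sucrose gradients, and the fractions of each gradient were combined into 2 pools. The light pool held free ribonucleoproteins, monosomes and disomes, and the heavy pool held fractions with 3 or more ribosomes. Libraries were made with a Smart-seq kit, which does not mark the strand. Per the submitters' processing notes, cutadapt, STAR and featureCounts were used with the GRCh38 build; their versions, the annotation release and the strand setting are not given in the sources used here.

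The authors deposited 1 table of raw counts, whole numbers of reads per gene, for 78932 Ensembl gene IDs in 8 libraries, and every column was matched to a sample by its name. Symbols were looked up by gene ID and found for 42179 IDs; 17214 of the 24289 tested genes had one. Gene positions and types were taken from GENCODE release 29 on GRCh38, which need not be the release the authors counted on. TALAM1, antisense to MALAT1, held 99.95% to 99.98% as many counts as MALAT1 in every library, so reads in overlapping genes were counted for both and antisense genes cannot be told from their partners. Values of antisense transcripts, overlapping genes, pseudogenes and other near-identical copies are therefore uncertain.

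Libraries were grouped by the labels into light and heavy pools of cells labelled control or OE (overexpression), with 1 library per group and line label, so n = 2 per group and the line label is the replicate. Nothing in the labels describes separate cultures within a line, and the pools of a line and genotype come from the same gradient as far as the labels say; p-values measure the spread between these libraries, and comparisons over both pools count the pools of a gradient as independent. To weigh this, 2 fits were added after the data were seen: edgeR on the counts of each gradient summed over its pools (4 gradients, 1 residual degree of freedom), and limma voom with the gradient as a random block. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the deposited counts with TMM scaling, filterByExpr and a model of group plus line label, which leaves 3 residual degrees of freedom. The biological coefficient of variation was 0.359 and the prior degrees of freedom were 10.1. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Contrasts compared OE with control in the heavy pool, in the light pool, between pools (the interaction) and over both pools, and also the heavy with the light pool and the line labels with each other. Per-library levels are CPM (counts scaled to a common library total) computed here with TMM scaling, not values the authors deposited; errors on log2 fold changes are standard errors (SE) derived from the quasi-likelihood F statistic.

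Of 36 gene lists fixed before the data were examined, 35 were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset inter-gene correlation of 0.01 and at least 5 tested members. Erythroid and megakaryocyte markers had fewer tested members and were not tested. The genes named by rule were OGFOD1, RPS23 and, per contrast, the 10 largest changes in each direction among genes past the threshold with a symbol, a mean of at least 10 CPM and the same direction under both line labels. For the line labels the rule took 5 genes per direction with the same direction in all 4 matched pairs. Where fewer than 5 genes passed, those of smallest unadjusted p filled up to 5 and are given as values. Up to 4 members of each list described were named by smallest p. Within a line label the planned comparison was a size rule with no test: genes that differed by at least 1 on the log2 scale in the same direction in both pools, at a mean of at least 10 CPM, were counted. After seeing the data, a line by genotype term was added to the fit of 8 libraries (2 residual degrees of freedom), and genotype plus pool was fitted within each line label (1 residual degree of freedom). Since a label holds 1 gradient per genotype, these fits measure the spread between pools of a gradient, so no difference is read from their p-values and within-label differences are given as values. The design, the list of alternatives and the naming rule were fixed before the data were examined.

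The line labels pair the libraries by design. Deviations of libraries from their group means, across genes, correlated between groups at -0.0981 to 0.624. Before use, the scripts were tested on simulated counts drawn from the real means and library sizes. For OE against control in the heavy pool, 86.6% of 67 genes changed 4-fold were recovered among 23317 genes. The figures were 83.6% for the light pool and 100% over both pools. For 4-fold changes confined to the heavy pool, the interaction test recovered 37.3% of 67 genes among 23458. For 4-fold line differences the test recovered 97% among 23475 genes, and for 4-fold pool differences 100% among 23445 genes. A changed list was called and 0 of 20 unchanged lists were. Unchanged genes called numbered 5 to 12 per comparison. The simulated genes and libraries were drawn independently, so these figures do not test correlation between genes or a spread shared within a gradient.

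Alternatives were DESeq2 1.42.0, limma voom, RLE and upper-quartile scaling, no low-count filter, a filter of at least 5 CPM in 4 libraries, no replicate block, a term for line by pool, a robust prior, fits to the 4 libraries of 1 pool, control libraries alone, and leaving out each library in turn with the tested genes kept. The leave-outs were first run with the genes filtered anew in the 7 libraries, which gave higher counts for most comparisons; the gene set was fixed after those counts were seen, and both versions are reported. Lists were also tested with an estimated correlation and with fry. The estimated correlation called no list in any comparison, so a call lost under it does not show that a list is unchanged. Control libraries alone were contrasted within the fit of 8 libraries, which supplied the spread. Protein-coding genes alone, and lists without the Molm13 control light library, were added after seeing the data. Total counts ran from 25741930 to 89373133 per library, so the limit that a count of 0 allows (3 counts) was 0.034 to 0.12 CPM. Confidence limits of 95% for single-library levels are exact binomial limits. They and this floor cover counting error only, since PCR reads without molecular identifiers are not independent molecules.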

Results

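RNA from light and heavy sucrose gradient pools was sequenced in 8 libraries to ask how OGFOD1 overexpression changes the translated RNA of leukaemia cells. OGFOD1 is a prolyl hydroxylase that modifies the ribosomal protein RPS23. Molm13 is an acute myeloid leukaemia line with a KMT2A rearrangement and an internal tandem duplication of FLT3, and U937 is a line of monocytic character. Each of the 4 groups (control light, control heavy, OE light, OE heavy) held 1 library labelled Molm13 and 1 labelled U937. Total counts per library ranged from 25741930 (Molm13 OE heavy) to 89373133 (Molm13 control light), and 27392 to 33915 genes had a count.

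OGFOD1 itself (ENSG00000087263, chromosome 16, 56451490 to 56479100, plus strand, GRCh38) was lower, not higher, in the libraries labelled OE. Its level was 41.4 ± 11.9 CPM in the control light pools and 13.4 ± 4.67 CPM in the light pools labelled OE (SD, n = 2), and 52.3 ± 11.2 CPM against 18.8 ± 9.08 CPM in the heavy pools. Under the Molm13 label it was 33 and 44.4 CPM in the control light and heavy libraries and 16.7 and 25.3 CPM in those labelled OE. Under the U937 label the values were 49.8 and 60.2 CPM against 10.1 and 12.4 CPM. As a share of all counts, the library with the lowest OGFOD1 level, U937 OE light, held 9.73 CPM (exact 95% limits 8.9 to 10.6) and the Molm13 control light library 34.9 CPM (33.7 to 36.1). Over both pools the log2 fold change was -1.60 (SE 0.30, adjusted p = 0.0178), lower in 4 of 4 matched pairs; with the pools of each gradient summed it was -1.60 with an adjusted p of 0.125. The direction of every comparison of genotypes below therefore goes by library labels that the target gene contradicts. The first 710 bases of OGFOD1 overlap NUDT21 on the opposite strand. RPS23 (ENSG00000186468, chromosome 5, 82273358 to 82278577, minus strand) had a log2 fold change of 0.14 over both pools (SE 0.34, adjusted p = 0.848).

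**Figure D1:**
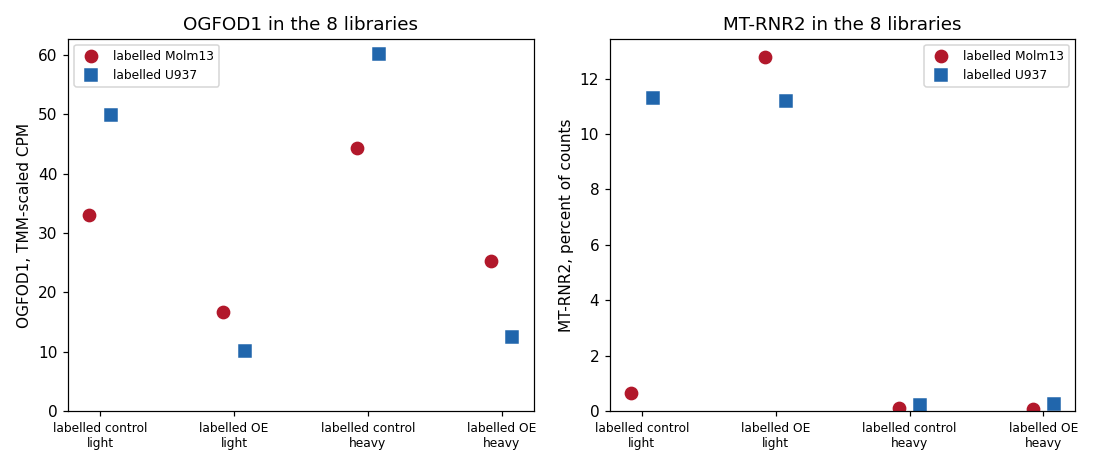
OGFOD1 in TMM-scaled CPM (left) and the mitochondrial rRNA MT-RNR2 in percent of counts (right) in each of the 8 libraries, with 1 point per library and no error bars, by label of line, genotype and pool. OGFOD1 lies at 33 to 60.2 CPM in the libraries labelled control and 10.1 to 25.3 CPM in those labelled OE, and MT-RNR2 is 0.646% in the Molm13 control light library against 11.2% to 12.8% in the other light libraries.

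Over both pools, the libraries labelled OE had lower RNA of genes for DNA replication and ribosome assembly and higher RNA of some hypoxia targets, interferon-induced genes and sterol synthesis enzymes. These are calls of single genes and of lists at a preset correlation. As lists, all 5 were lost with an estimated correlation, a setting that called no list in any comparison. With an estimated correlation the adjusted p was 0.365 for replication, ribosome biogenesis and interferon, 0.506 for hypoxia and 0.575 for sterol synthesis. The gene calls count the pools of a gradient as independent libraries; with the counts of each gradient summed, edgeR called 0 genes (4186 at an unadjusted p under 0.05, smallest adjusted p = 0.117), so they hold for the main fit and not for gradients as the unit. The replicative helicase subunit MCM6 fell by 2.04 on the log2 scale (SE 0.27, adjusted p = 0.00982), and the replication factors MCM10 (-1.90, SE 0.26) and CLSPN (-1.86, SE 0.26) and the cell cycle phosphatase CDC25A (-1.71, SE 0.27) fell with it. Other genes among the largest decreases were the neutrophil protein gene S100A8 (-1.89), HPDL (-1.79), VAT1L (-1.73), the neuropeptide gene GAL (-1.72), the RNA-binding protein gene HNRNPAB (-1.68) and the pseudogene HMGB1P5 (-1.70). Among the genes named by rule, the vasodilator peptide gene ADM rose most, with a log2 fold change of 2.97 (SE 0.64, adjusted p = 0.0279). The inhibitory Fc receptor FCGR2B (2.96, SE 0.69), the G protein signalling regulator RGS1 (2.86, SE 0.49), TMEM158 (2.54), the chemokine CCL24 (2.53), the tetraspanin CD9 (2.50), the antiproliferative gene BTG2 (2.48, SE 0.34), GPRC5C (2.32), YPEL3 (2.28) and TBC1D30 (2.24) also rose. Several of these values hang on the Molm13 control light library: without it ADM was at 4.89, FCGR2B at 4.11, CCL24 at 4.08, CD9 at 3.64 and TBC1D30 at 2.85.

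Among gene lists, ribosome biogenesis factors had 49 of 50 members with negative values and a median log2 fold change of -0.83; 19 fell over all genes tested and 41 when adjusted over the list alone, among them RRP1B (-1.37), TCOF1 (-1.45), LYAR (-1.44) and UTP20 (-1.68). The list was past the threshold with camera and not with an estimated correlation (adjusted p = 0.365 with an estimated correlation). Of 41 DNA replication genes 24 fell, 33 when adjusted over the list alone, with a median of -1.04; MCM3 (-1.65) and POLE2 (-1.51) were among them, and the list had an adjusted p = 0.365 with an estimated correlation. Mitotic genes had a median of -0.57 and 5 of 36 fell (15 adjusted over the list alone), including MKI67 (-1.11) and CENPF (-1.09). MYC and its targets had a median of -0.61 and 4 of 25 fell (8 adjusted over the list alone), led by the pyrimidine synthesis enzyme CAD (-1.58). Cytosolic chaperones had a median of -0.40, with 4 of 28 lower and 1 higher (9 and 1 adjusted over the list alone), and HSP90AA1 at -1.41. Translation initiation and termination factors had a median of -0.39 and 5 of 38 fell (7 adjusted over the list alone), led by EIF5B (-1.38). Mitotic, MYC, chaperone and initiation factor lists each had an adjusted p = 0.365 with an estimated correlation. Proteasome subunits had a median of -0.72 and 4 of 35 fell, 20 adjusted over the list alone (adjusted p = 0.575 with an estimated correlation).

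Hypoxia targets were positive for 22 of 22 genes with a median of 1.25; 7 rose over all genes and 19 when adjusted over the list alone, with the collagen prolyl hydroxylase P4HA1 at 1.99 (adjusted p = 0.506 for the list with an estimated correlation). Of 40 interferon-induced genes 7 rose, 17 when adjusted over the list alone, among them IFIT3 (1.93), IFIT2 (2.13) and RSAD2 (2.39), and the list had an adjusted p = 0.365 with an estimated correlation. Of 24 cholesterol synthesis genes 5 rose, 8 when adjusted over the list alone, including MSMO1 (1.43), and the list had an adjusted p = 0.575 with an estimated correlation. Under the U937 label the ADM, FCGR2B and CD9 differences were 4.69, 5.04 and 4.02 on the log2 scale and under the Molm13 label 2.40, 1.26 and 1.39. In the Molm13 light pair ADM and FCGR2B did not rise, each at -0.25, against 5.05 and 2.77 in the heavy pair. A line by genotype term, fitted after the data were seen, gave adjusted p = 0.0161 for the difference of the line labels in FCGR2B, 0.966 in ADM and 0.27 in CD9. That fit counts pools of a gradient as independent, and no difference between labels is read from it.

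In total 487 genes rose and 574 fell of 24289 tested over both pools; upper-quartile scaling gave 61% higher calls in place of 45.9%. The count of 1061 rested on single libraries. It was 3126 without Molm13 control light, 322 without Molm13 control heavy, 690 without Molm13 OE light, 134 without Molm13 OE heavy, 1994 without U937 control light, 55 without U937 control heavy, 220 without U937 OE light and 0 without U937 OE heavy. With the gradient as a random block limma voom called 3172, DESeq2 called 2655 and limma voom with no block on gradients 1244.

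**Figure D2:**
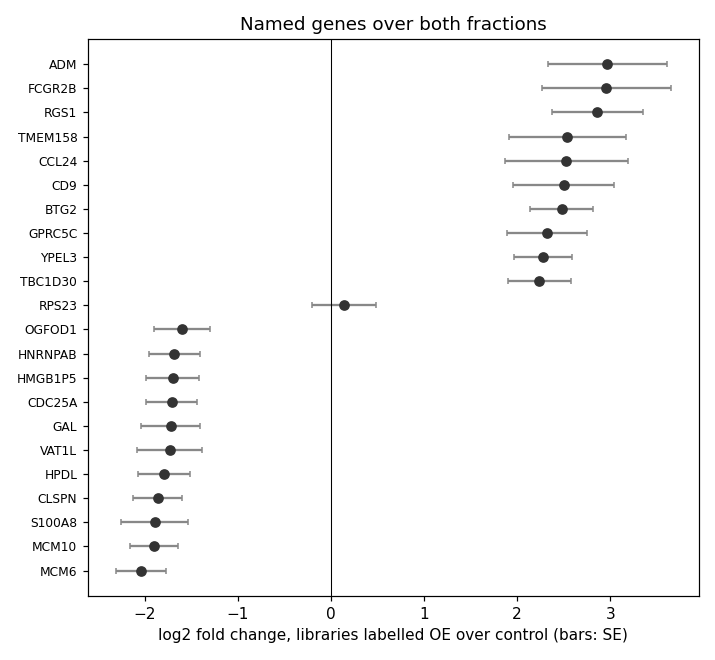
Log2 fold changes of the genes named by rule, libraries labelled OE over libraries labelled control across both pools (points), with their standard errors (bars). Values run from -2.04 for MCM6 to 2.97 for ADM, and OGFOD1 lies at -1.60.

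In the heavy pools, where the question is which RNAs on polysomes differ with OGFOD1 overexpression, the libraries labelled OE had lower median values of replication and ribosome assembly genes and higher ones of hypoxia and interferon genes. None of these lists kept its call (adjusted p = 0.398 for replication, ribosome biogenesis and interferon and 0.544 for hypoxia with an estimated correlation). That setting called no list in any comparison. With edgeR, 1 gene passed the threshold over all genes, DYNC1I1, a dynein intermediate chain gene (-3.57, SE 0.44, adjusted p = 0.046), which was named after its value was seen. Its mean was 6.45 CPM. The genes of smallest p that follow did not pass (adjusted p = 0.074 for each) and are given as values. They were SERPINI1 (3.20), TPST2 (2.47), ARRDC3 (2.18), TBC1D30 (2.87) and RGS2 (2.77) on the positive side, and the replication genes GINS4 (-1.93), CLSPN (-1.99) and POLA1 (-1.92) with RBM28 (-1.78) and the antisense transcript RRM1-AS1 (-1.82) on the negative side. Without the Molm13 control light library, which this comparison does not use, their values hardly moved, with SERPINI1 at 3.16 and GINS4 at -1.94.

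Of 41 DNA replication genes 27 fell when adjusted over the list alone and 0 over all genes, with negative values for 41 of 41 and an adjusted p = 0.398 with an estimated correlation. Ribosome biogenesis had 18 of 50 lower when adjusted over the list alone, with UTP20 at -2.50 (adjusted p = 0.398 with an estimated correlation). Hypoxia targets had a median of 1.88 and 17 of 22 higher when adjusted over the list alone, with ADM at 4.78 and BNIP3 at 2.24 (adjusted p = 0.544 with an estimated correlation). Interferon-induced genes had 15 of 40 higher when adjusted over the list alone, with RSAD2 at 4.42 and OAS1 at 2.89 (adjusted p = 0.398 with an estimated correlation). Ribosomal protein genes were negative for 79 of 79 members with a median of -0.61, none past the threshold even when adjusted over the list alone (adjusted p = 0.616 with an estimated correlation). RPS23 was at -0.40 (SE 0.48) and OGFOD1 at -1.52 (SE 0.42, adjusted p = 0.125).

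At an unadjusted p under 0.05, 3670 genes differed in the heavy pools, against 1214 expected by chance; DESeq2 called 994 and limma voom 0. The count was 1447 without Molm13 control light, 1500 without U937 control light, 147 without Molm13 OE light, 45 without U937 OE light, and 0 without Molm13 control heavy, Molm13 OE heavy or U937 OE heavy.

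In the light pools, the libraries labelled OE had lower median values of replication, ribosome assembly, mitochondrial ribosome and proteasome genes. None of these lists kept its call (adjusted p = 0.625 for the first 2 and 0.638 for the others with an estimated correlation). That setting called no list in any comparison. No gene passed the threshold over all genes with edgeR, and the genes of smallest p are given as values (adjusted p = 0.138 for each). On the positive side these were BTG2 (2.63), TRIQK (1.86), YPEL3 (2.25), the kinase gene RIOK3 (2.03) and PCBP2-OT1 (1.81). Without the Molm13 control light library BTG2 was at 3.29, YPEL3 at 2.83 and RIOK3 at 2.49, but TRIQK at 1.65 and PCBP2-OT1 at 1.80. On the negative side the genes of smallest p included the mitochondrial ATPase gene ATAD3A (-1.83), the splicing factor gene PRPF19 (-1.81) and MCM6 (-2.11). OGFOD1 was at -1.67 (SE 0.42, adjusted p = 0.146) and RPS23 at 0.69 (SE 0.48).

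Of 41 replication genes 27 fell and 1 rose when adjusted over the list alone, and 27 of 50 ribosome biogenesis genes fell on that scale, led by EBNA1BP2 (-2.17); both lists had an adjusted p = 0.625 with an estimated correlation. Mitochondrial ribosomal proteins had a median of -0.99 with 42 of 76 lower, and proteasome subunits -0.94 with 15 of 35 lower, each adjusted over the list alone, against 0 over all genes; both had an adjusted p = 0.638 with an estimated correlation. Without the Molm13 control light library, an alternative added after the data were seen, these medians were -0.63 and -0.70. The 13 mitochondrially encoded mRNAs had a median of 0.51 (adjusted p = 0.744 with an estimated correlation) and -0.50 without that library.

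At an unadjusted p under 0.05, 3604 genes differed in the light pools; DESeq2 called 930 and limma voom 0. The edgeR count was 514 without Molm13 control light and 1471 without U937 control light.

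The interaction asks whether OE moved RNAs between the light and heavy pools. No gene passed with edgeR; 1431 genes had an unadjusted p under 0.05 against 1214 by chance, DESeq2 called 6 and limma voom 0. The genes of smallest p, each at an adjusted p of 0.791, were EMC7 (2.21), TMEM35B (2.48), the lactate transporter SLC16A3 (2.53), LAPTM4A (1.74) and the aquaporin AQP3 (2.57) on the positive side. Without the Molm13 control light library TMEM35B was at 1.61, SLC16A3 at 1.5 and AQP3 at 1.46. RRM1-AS1 (-2.41), PCBP2-OT1 (-2.53), the pseudogene NPM1P27 (-2.16), the ribonucleotide reductase gene RRM1 (-2) and the origin recognition gene ORC1 (-1.77) were on the negative side. Ribosomal protein genes had a median of -0.77 with 75 of 79 negative, and other mRNAs with a 5′ terminal oligopyrimidine tract, such as PABPC1 (-2.10) and EIF2S3 (-1.77), a median of -1.17 with 19 of 22 negative. Nuclear genes of oxidative phosphorylation had a median of 0.81 with 71 of 76 positive. For each of these 3 lists the adjusted p = 0.747 with an estimated correlation, and 0 members passed when adjusted over the list alone.

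Without the Molm13 control light library the oxidative phosphorylation median was 0.20 and the ribosomal protein median -0.62, and the number of lists past the threshold was 7 in place of 19. Without the U937 control light library 975 genes passed. RPS23 had an interaction value of -1.09 (SE 0.68, adjusted p = 0.792) and OGFOD1 of 0.15 (SE 0.58, adjusted p = 0.97).

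Heavy polysomes and light pools differed most in mitochondrial RNA, which was concentrated in the light pools. The mitochondrial rRNA MT-RNR2 was lower in the heavy pools by a log2 fold change of -5.76 (SE 0.75, adjusted p = 0.000657), and MT-ND3 (-4.96), MT-ATP6 (-4.56), MT-CO3 (-4.38), MT-CO2 (-4.37), MT-ATP8 (-4.14), MT-ND2 (-3.83), the tRNA genes MT-TG (-3.85) and MT-TS1 (-3.73) and the nuclear copy MTATP6P1 (-4.61) were lower with it. All 13 mitochondrially encoded mRNAs were lower in the heavy pools, with a median of -3.55 (adjusted p = 0.544 for the list with an estimated correlation). SNX32 (2.89), the oxidase subunit CYBA (2.84, SE 0.56, adjusted p = 0.00328), the centromere protein gene CENPW (2.64), the prefoldin subunit PFDN6 (2.64), the proteasome subunit PSMB3 (2.63) and the deoxyhypusine hydroxylase DOHH (2.60) were higher in the heavy pools. So were MIR3917 (2.85), HMGB1P5 (2.71), QKILA (2.68) and H2AZ1-DT (2.60), which are noncoding or lie at other genes. Without the Molm13 control light library CYBA was at 3.98, SNX32 at 3.80, MIR3917 at 3.62, H2AZ1-DT at 3.45 and QKILA at 3.38.

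Host genes of small nucleolar RNAs, which are spliced but poorly translated, were lower in the heavy pools for 19 of 20 members, among them SNHG4 (-2.64), DANCR (-2.57) and SNHG16 (-2.38). Of 15 nuclear noncoding RNAs 9 were lower (13 adjusted over the list alone), with NEAT1 at -2.66. Terminal oligopyrimidine mRNAs outside the ribosome had 14 of 22 lower (15 adjusted over the list alone), with PABPC1 at -3.15 and EIF4B at -1.97. These 3 lists each had an adjusted p = 0.544 with an estimated correlation. Ribosomal protein genes had 19 of 79 lower and 3 higher, with RPL41 at -2.47 and RPS20 at -2.18 (adjusted p = 0.648 with an estimated correlation).

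Proteasome subunits were higher in the heavy pools for 31 of 35 members (32 adjusted over the list alone), with a median of 1.34, and mitochondrial ribosomal proteins for 51 of 76 (60 adjusted over the list alone), with MRPL16 at 1.84; both lists had an adjusted p = 0.544 with an estimated correlation. Ribosome biogenesis genes were higher for 30 of 50 (33 adjusted over the list alone), led by EBNA1BP2 at 2.41 (adjusted p = 0.544 with an estimated correlation). Nuclear oxidative phosphorylation genes were higher for 44 of 76 and lower for 2, with ATP5MC1 at 2.27 and UQCR11 at -2.22 (adjusted p = 0.579 with an estimated correlation). OGFOD1 (0.41, SE 0.29) and RPS23 (-0.70, SE 0.34) did not pass the threshold.

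In all, 3833 genes were higher and 3104 lower in the heavy pools; 39.7% of calls were higher with upper-quartile scaling in place of 55.3%. The contrast of the control libraries alone, within the fit of 8 libraries, gave 262 genes. Of the library exclusions, 4 moved the count of 6937 by over 1.5 times: it was 3796 without Molm13 OE light, 3602 without Molm13 OE heavy, 3654 without U937 control heavy and 3601 without U937 OE heavy.

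**Figure D3:**
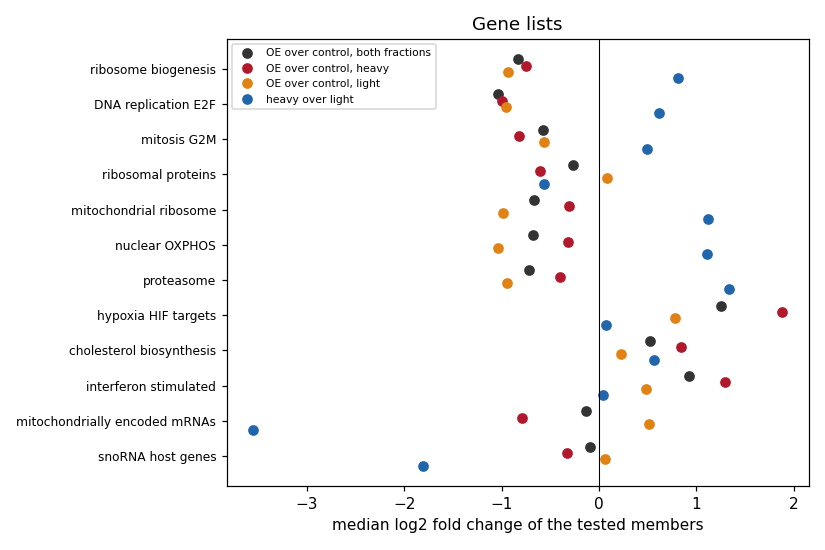
Median log2 fold change of the tested members of 12 gene lists (points, no error bars) for libraries labelled OE over control in both pools, the heavy pools and the light pools, and for heavy over light pools. Ribosome biogenesis lies at -0.83 and hypoxia targets at 1.25 over both pools, and mitochondrially encoded mRNAs at -3.55 in heavy over light pools.

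Between the libraries labelled Molm13 and U937, no gene passed the threshold with edgeR, although 2862 genes had an unadjusted p under 0.05 (smallest adjusted p = 0.0841). DESeq2 called 303 genes, limma voom 1, and limma voom with the gradient as a random block 54. The genes of smallest p by rule, given as values for Molm13 over U937, were the granule protein gene BPI (1.54, SE 0.23, adjusted p = 0.118), H3P6 (1.49), the desaturase gene FADS2 (1.20), OCSTAMP (1.62) and LINC03040 (2.09) on the positive side. MTCO1P40 (-2.15), NACA3P (-1.21), the myeloperoxidase gene MPO (-1.18), TP53INP1 (-1.25) and DNAJB9 (-1.15) were on the negative side. No gene lay at 10 CPM or more in all libraries of a line label and under 1 CPM in all of the other. OGFOD1 was at 0.17 (SE 0.30) and RPS23 at -0.27 (SE 0.34). The count was 11 without Molm13 control light, 3 without Molm13 OE light, 52 without U937 control light and 0 without any other library.

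The OE minus control differences of the line labels were compared across genes, which are not independent replicates. Over genes of all levels, Pearson's r was 0.365 in the heavy pools, 0.106 in the light pools and 0.393 over both pools, and 63%, 54.8% and 66.4% of genes had the same sign. For the change between pools r was -0.00503. All but the heavy-pool values use the Molm13 control light library, which lay between the other groups, so they do not measure the lines alone.

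The line labels were compared by a size rule with no test, since each label holds 1 gradient per genotype. By this rule 41 genes were higher and 68 lower under Molm13, and 400 higher and 313 lower under U937. Both labels shared 45 genes. Of the 109 genes under Molm13, 97 had the same direction in both pools under U937, and 410 of the 713 under U937 had it under Molm13. The Molm13 light difference uses the Molm13 control light library, which lay between the other groups, so these counts do not compare the lines alone. The largest mean differences under U937 were the carbonic anhydrase CA9 (5.82), FCGR2B (5.04), the creatine transporter SLC6A8 (4.86), the haem oxygenase HMOX1 (4.78) and ADM (4.69) on the positive side. MS4A3 (-2.96), VAT1L (-2.63), the helicase gene HELLS (-2.48), MCM6 (-2.40) and S100A8 (-2.33) were on the negative side. Under Molm13 they were ITGA6-AS1 (2.05), the adenylate kinase AK4 (1.88), BTG2 (1.66), IL7R (1.66) and ARRDC3 (1.65), and RRBP1 (-1.80), SCRIB (-1.79), HMGB1P5 (-1.73), SESN2 (-1.66) and TCOF1 (-1.66).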

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

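The interleukin 7 receptor gene IL7R was higher in OE than in control in the libraries labelled Molm13, by 1.48 (heavy) and 1.84 (light) on the log2 scale, and lower in those labelled U937, at -0.73 and -1.35; the difference of the means was 2.70. The stress-response gene SESN2 was at -2.12 and -1.20 under Molm13 and at 0.14 in both pools under U937. The difference of its means was -1.80, and it was singled out because the signs differ, although its U937 values are close to 0. The light values under Molm13 use the Molm13 control light library, which lay between the other groups. Of the 109 genes under Molm13 by the size rule, 8 had the opposite direction in both pools under U937. A line by genotype term, fitted after the values were seen with pools counted as independent, gave an adjusted p of 0.0406 for IL7R and 0.288 for SESN2. With gradients as the unit the differences were not tested, since each line label holds 1 gradient per genotype, so no difference is read from that fit.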

How the results depend on the processing

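Protein-coding genes alone, the lists without the Molm13 control light library, keeping the same 24289 genes in the leave-outs, and the fits that take the gradient into account were chosen after seeing the data; the other settings were planned. The number of genes that differ with the OE label in the heavy pools was 1 in the main fit, 994 with DESeq2, 1039 with no low-count filter, 180 with at least 5 CPM in 4 libraries, 1683 with the 4 libraries of that pool, 255 with protein-coding genes only, and 0 with no replicate block, with a line by pool term, with limma voom, with the gradient as a random block or with the robust prior. In the light pools it was 0, against 930 with DESeq2, 560 with no filter and 24 with the 4 libraries of that pool. The interaction gave 0, against 6 with DESeq2 and 74 with no filter. Over both pools it was 1061, against 2655 with DESeq2, 2299 with no filter, 116 with no replicate block, 316 with the line by pool term, 3172 with the gradient as a random block and 0 with the counts of the pools of a gradient summed. The summed fit left OGFOD1 at -1.60, ADM at 2.90 and MCM6 at -2, each short of the threshold on 1 residual degree of freedom. The random block had a consensus correlation of -0.258, and a negative value raises the precision of comparisons between gradients, so its higher count is no evidence that the pools are independent. Heavy against light gave 6937, against 262 for the control libraries contrasted within the same fit and 4515 with protein-coding genes only. The line labels gave 0, against 303 with DESeq2, 412 with no filter, 54 with the gradient as a random block, and 1 with the filter of 5 CPM or with limma voom. With no filter 44611 genes were tested in place of 24289 and the estimated prior degrees of freedom became infinite; otherwise the cause was not tested. Leaving out each library in turn gave 0 to 1500 genes in the heavy pools, 0 to 1471 in the light pools, 0 to 975 for the interaction, 0 to 3126 over both pools, 3601 to 9241 for heavy against light and 0 to 52 for the line labels; the lone library of a group is then assumed to vary like the others. The first run of the leave-outs, with genes filtered anew in the 7 libraries, gave 0 to 1882, 0 to 1926, 0 to 1371, 18 to 3567, 3801 to 9502 and 0 to 131 in the same order, so the kept gene set is the lower of the 2 versions at both ends or equal. Leaving out either control light library cut the biological coefficient of variation from 0.359 to 0.301 and raised the prior degrees of freedom from 10.1 to 25.5 (Molm13) or 26.2 (U937), so this rise alone does not tell which of the pair is out of place. Of the 1061 genes over both pools, 1047 were also called without Molm13 control light.

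With an estimated correlation 0 lists passed in every comparison, where the preset correlation gave 25 (heavy pools), 18 (light pools), 19 (interaction), 19 (both pools), 23 (heavy against light) and 18 (line labels). Even the mitochondrially encoded mRNAs, all lower in the heavy pools, were not called with an estimated correlation. A call lost under that setting therefore does not show that a list is unchanged. Directional fry gave 4, 0, 0, 6, 15 and 0, and mixed fry 15, 9 and 0 in the first 3 comparisons and 1 for the line labels. Leaving out libraries gave 14 to 25 lists in the heavy pools, 7 to 24 for the interaction and 10 to 18 for the line labels. List medians turned sign in 3 cases: in the heavy pools without U937 control heavy, the mitochondrial ribosome (leave-outs -0.69 to 0.04) and nuclear oxidative phosphorylation (-0.67 to 0.16), and in the light pools without Molm13 control light, mitochondrially encoded mRNAs (-0.50 to 1.96). OGFOD1 turned sign in the interaction with no filter (0), with protein-coding genes only (-0.02) and in 4 leave-outs (-0.52, -0.46, -0.21 and -0.17; highest 0.62). In leave-outs of the line contrast it ran from -0.11 to 0.44, with 4 negative values (2 at -0.11 and 2 at -0.02), and RPS23 over both pools from -0.07 to 0.32, with -0.01 as the other. None of these gene values had passed the threshold. Over 92 named gene results, 1475 alternative values kept direction and side of the threshold, 106 lost the call, 194 gained it and the 12 given above turned sign. Agreement of the line labels across genes at 10 and 50 CPM had an r of 0.571 and 0.596 in the heavy pools, 0.187 and 0.242 in the light pools, 0.609 and 0.612 over both, 0.899 and 0.906 for heavy against light, and -0.00907 and 0.12 for the change between pools. Single-line counts fell from 109 to 5 (Molm13) and from 713 to 202 (U937) at 1.5 on the log2 scale, and to 35 and 283 at 50 CPM. Upper-quartile scaling moved the median of all genes from -0.053 to 0.105 in the light pools, from 0.081 to -0.088 for the interaction and from -0.037 to -0.221 for heavy against light, so list medians smaller than these shifts depend on the scaling.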

Other observations

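Single genes of other groups differed over both pools with the OE label; none of these groups passed with an estimated correlation. Of 26 inflammatory genes of the NF-kB pathway 2 rose, the chemokine CCL20 (1.59) and the adhesion molecule ICAM1 (1.99), 11 adjusted over the list alone (adjusted p = 0.599 with an estimated correlation). Of 74 KRAB zinc finger genes 6 rose and 1 fell (12 and 2 adjusted over the list alone), with ZNF585A at 1.68 and ZNF544 at 2.00 (adjusted p = 0.693 with an estimated correlation). Of 23 p53 targets BTG2, FAS (0.94) and TP53INP1 (0.99) rose, 4 adjusted over the list alone (adjusted p = 0.65 with an estimated correlation). The serine synthesis enzyme PSAT1 fell by 1.30, as did GPT2 (-0.99) and the arginine transporter SLC7A1 (-0.96), in a stress-response list of 36 genes that did not pass (10 lower and 6 higher adjusted over the list alone). Of 7 tested epithelial and fibroblast markers, the keratins KRT18 (-1.45) and KRT8 (-1.35) fell; the list did not pass. A call for FN1 rests on counts of 0 in the heavy pools labelled OE at levels of at most 0.885 CPM and is not read as a change.

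Coding length was tested against the pool differences in 7966 nuclear protein-coding genes of at least 10 CPM (98.4% had a length in GENCODE release 29), on the hypothesis that longer coding sequences hold more ribosomes; both correlations of length were planned before they were seen, and the tests within U937 and without single libraries were chosen after. Across genes, which are not replicates, Spearman's rho with the heavy minus light change was -0.139, the opposite sign. With each library left out in turn it ran from -0.215 to -0.0464. The medians were not in order of length: 0.23 for genes of up to 300 coding bases, 0.46 for 601 to 1200, 0.12 for 2401 to 4800 and 0.18 for 4801 or more. With the interaction rho was -0.436. This was past the size of 0.2 set in advance for a movement of long coding sequences with the OE label, so the planned bound was met. Under the U937 label, however, the heavy minus light rho was -0.205 in control and -0.199 in OE, a difference of 0.00631 (95% bootstrap interval over genes -0.00457 to 0.0173). The Molm13 pairs differed, at 0.385 for control and -0.262 for OE. With each library left out in turn the interaction rho ran from -0.516 to -0.232. It was -0.282 without Molm13 control light and -0.232 without Molm13 control heavy, but each of these fits keeps the other library of that gradient. Of the pairs, only Molm13 control had a positive rho, so the interaction rho may rest on that 1 gradient.

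All tests of the next 3 patterns, and their bounds, were chosen after values were seen. The bound for NUDT21 was first a fall of at least 0.5 of the OGFOD1 change, which left that explanation undecided, and was then revised to the full change. The bound of 0.7 for the mix was set after a first look at weighted sums.

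OGFOD1 lay lower in the libraries labelled OE. An introduced copy unseen by the gene counts, with the gene of the cells unchanged, would leave OGFOD1 level. The OGFOD1 change of -1.60 (-0.90 under Molm13, -2.29 under U937) is below that by over 2 standard errors of the main fit. That fit counts the pools of a gradient as independent, and with gradients summed the change did not pass the threshold. The values therefore go against this version only with pools as the unit. An unseen copy with a fall of the gene of the cells stays open. Reads of the overlapping gene NUDT21 cannot bring a fall larger than its own change of -0.30. By the revised bound, which uses standard errors of the main fit, they are argued against. An exchange of the OE and control labels needs OGFOD1 higher in the library labelled control in all pairs, which 4 of 4 showed, but an exchange and a lowered OGFOD1 under correct labels cannot be told apart because both give this value. The library names carry Scr for the libraries labelled control and OE for the others, so they repeat the labels and do not decide this. A response of the gene to the vector stays open, untested.

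The line labels did not part the libraries. Cells of 1 origin under both line labels would give no gene at 10 CPM or more in all libraries of a label and under 1 CPM in all of the other. The count was 0, but that is the observation itself, so whether both labels hold the same line cannot be told apart from a difference too small for this rule. With a gap of 8-fold in place of the 1 CPM limit the count was also 0, and how many such genes the lines should show was not known. By the median log2 difference each library lay closest to a library of the other line label, but libraries of a label never share both genotype and pool. By Pearson's r of log2 CPM this did not hold for every library. Molm13 control light was closest to Molm13 control heavy (0.966, against 0.965 for U937 control heavy). U937 control light was closest to U937 OE light (0.943, against 0.942 for Molm13 OE light). Line labels exchanged for some libraries only would show on-off genes in another of the 127 splits of the 8 libraries only if the lines differ by such genes; the highest number was 0, so this stays open too. Too little precision stays open as well: the same fit called 6937 genes between pools, but that contrast lies within gradients and does not measure the precision between line labels. In simulated counts 97% of 4-fold line differences were recovered, but the pools were drawn as independent, so that does not measure it either. A real but smaller line difference also stays open, since DESeq2 called 303 genes.

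The Molm13 control light library lay between the other groups. Loss of mitochondrial RNA alone would keep its nuclear light-enriched genes at the light level, but their median share of that level was 0.281 (95% bootstrap interval 0.266 to 0.314, 285 genes). Carry-over of control heavy RNA alone was expected to keep genotype genes of this library at the control level. Over 703 genes that part the U937 genotypes its median position (0 control, 1 OE) was 0.596, against 0.301 for Molm13 control heavy. The position was measured against the U937 control light library, so carry-over would itself move genes that differ between pools. The 703 genes were also picked for their U937 differences, so this test cannot exclude carry-over. A weighted sum of other libraries, led by Molm13 OE heavy with weight 0.404, cut the residual of the Molm13 control light library. This residual was 0.452 of that of the best single library (lowest ratio elsewhere 0.723). Any library lying between others is better fitted by a sum, so this restates the pattern and leaves a mix of material or reads open for its nuclear RNA. The same weights would give MT-RNR2 at 4.67% where 0.646% was measured, which argues against a mix as the source of its mitochondrial RNA; no biological explanation was tested.

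Other splits of the 8 libraries into 4 and 4 were fitted with the remaining labels as terms, 33 per comparison. For the OE label over both pools 1 of 33 splits, the real one, gave as many genes (695, highest other 14). Most of these splits do not part all pairs of the same line and pool, and the fits count the pools of a gradient as independent. Only 3 splits keep gradients whole, and the one by line label could not be fitted beside the line term, so these are too few for a share under 0.05. Among the 8 splits that part all 4 pairs of the same line and pool the highest other was also 14, and these are too few for a share under 0.05. For heavy against light 1 of 33 did (6336; highest other 0). For the line labels all 33 gave at least the real 0, which any split does, so that comparison decides nothing. The highest other, 205, set Molm13 control light, control heavy and OE heavy with U937 OE heavy, which may reflect a structure of the libraries other than the line labels. This split was noted as the highest, and its cause was not tested. For counts of lists, 13 of 33 splits gave as many as the 19 for the OE label (highest other 22), 2 of 33 as many as the 23 for heavy against light (highest other 23) and 13 of 33 as many as the 16 for the line labels (highest other 24), so chance cannot be excluded for these counts of lists.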
